A study of Mus musculus with 6 samples.

How the data were processed

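Total RNA from mouse liver tumors was made into stranded total RNA libraries, per the labels' protocols. The deposited table holds expected counts per gene, estimated reads that are not scaled to library size; cutadapt, STAR, Picard and RSEM are named, per the submitters' processing notes, with no versions given there, and the genome build is mm10. The annotation release is not given in the sources used here. Of the values, 12.3% were not whole (tolerance 0). The table has 47643 genes as versioned Ensembl IDs joined to symbols, and 47224 matched a GENCODE annotation of the same build, from which coordinates were taken (1-based); 419 did not.

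Expected counts were rounded to whole numbers. Groups were taken from the labels: 3 vehicle and 3 GSK3326595 libraries, with totals from 25814339 to 33621083 expected counts. The comparison was GSK3326595 against vehicle, and a positive log2 difference means higher in GSK3326595. Genes were kept with the edgeR filter filterByExpr (minimum count 10), which left 17012. They were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.409. The SE is the absolute log2 difference divided by the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run beside it.

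Gene lists, written from textbook knowledge before the data were examined, were tested with camera (preset correlation 0.01) on log2 CPM where at least 5 members were tested, with adjustment over all lists; the platelet list had too few. Camera with an estimated correlation and fry, in its directional and mixed forms, were also run. Counts adjusted over the list alone use edgeR's p within each list. Named genes followed a rule fixed before the data were examined. Prmt5, Myc and Hnf4a were always named. The 10 largest changes per direction among called genes were to be named, or the 5 genes of smallest p where fewer than 5 qualified, which applied here. Up to 4 members of smallest p were named from each list described.

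The edgeR, limma-voom, DESeq2, camera and directional fry tests were tested on simulated counts with known changes. Each gene was drawn independently there, so the simulation could not show how camera or fry behave when list members vary together. The mixed fry test, the permutation and bootstrap tests and the fit with sample quality weights were not simulated. Alternatives were other scaling, filters, thresholds and tools, leaving out mitochondrial and rRNA genes, a replicate block, and leaving out each library in turn. All 10 splits of the 6 libraries into 3 and 3 were refitted. Permutation tests over genes used 100000 resamples, and the test of X-linked genes 10000.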

Results

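Bulk RNA sequencing was performed on liver tumors of FVB/N mice carrying LAP-tTA and tetO-MYC, a system in which a MYC transgene is held off in the liver by doxycycline and comes on when the drug is withdrawn. Doxycycline was given at 100 mg/L until 4 weeks of age, MYC was then on for 8 weeks, and the mice next received vehicle or GSK3326595, an inhibitor of the arginine methyltransferase PRMT5, at 50 mg/kg/day for 2 weeks. There were 3 vehicle and 3 GSK3326595 libraries. The vehicle libraries held 33621083, 31480006 and 32188866 expected counts and the GSK3326595 libraries 30234273, 32427490 and 25814339. The labels number the replicates without stating that each came from a separate animal, so p-values measure the spread between these samples. On the first principal component, with 38.1% of the variance, GSK3326595 replicate 2 lay at 103.1 and the other 5 libraries between -50.2 and 9.37.

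**Figure D1:**
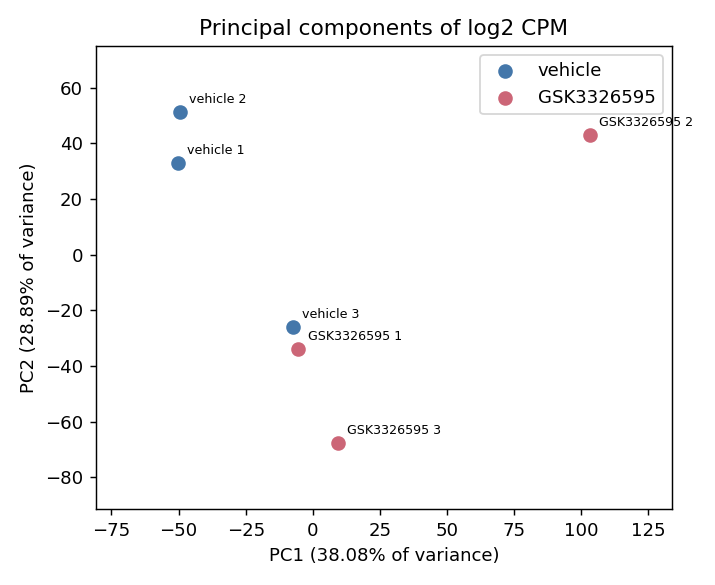
Scores of the 6 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, with 38.1% and 28.9% of the variance. Each point is a library, coloured by group, and GSK3326595 replicate 2 stands alone at 103.1 on the first.

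The comparison asks how inhibition of PRMT5 alters gene expression in MYC-driven liver tumors. No single gene passed edgeR's threshold over all 17012 genes tested, while DESeq2 called 204 higher and 111 lower. Prmt5 itself (ENSMUSG00000023110.12; chromosome 14, 54507187 to 54517525, minus strand) had 67.9 ± 18.1 CPM in vehicle and 92.4 ± 39.4 CPM in GSK3326595 (SD, n = 3 each), a log2 difference of 0.44 ± 0.37 (SE; edgeR adjusted p = 0.753). The mouse Myc gene (chromosome 15) had 5.11 ± 3.33 against 2.87 ± 0.913 CPM (log2 difference -0.83 ± 0.52, edgeR adjusted p = 0.665). The MYC transgene was not analysed here, and whether its reads were counted under mouse Myc was not tested. Hnf4a, a transcription factor of hepatocyte identity, had 521 ± 21.7 against 472 ± 55.6 CPM (-0.14 ± 0.17, edgeR adjusted p = 0.848).

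By edgeR, 0 genes were higher and 0 lower in GSK3326595 at the adjusted threshold, and the smallest adjusted p was 0.455. At an unadjusted p under 0.05, 927 genes were higher and 648 lower, 1575 in all where chance gives 851. With no scaling beyond total counts these were 1142 and 430, as the median gene then lay at a log2 difference of 0.12. These counts depended on single libraries: they were 347 higher and 250 lower without vehicle replicate 1, 745 and 241 without vehicle replicate 2, and 1629 and 655 without GSK3326595 replicate 3. Without GSK3326595 replicate 1 the excess turned, with 886 higher and 961 lower. With no filter on low counts they were 1547 and 715 of 27765 genes. The groups did not overlap in 2447 genes, 14.4% of those tested, against the 10% that chance gives. DESeq2 called 204 genes higher and 111 lower, and limma-voom 0 and 0. On counts simulated for this comparison over 17012 genes, edgeR recovered 1.49% of genes changed 2-fold, 47.8% of those changed 4-fold and 97.0% of those changed 16-fold, with 4 calls among unchanged genes. DESeq2 recovered 9 of 67, 60 of 67 and 65 of 66 (13.4%, 89.6% and 98.5%), but made 65 calls among unchanged genes. A larger share of its simulated calls was thus false than the threshold of 0.05 allows. The counts were drawn a single time, with dispersions estimated by edgeR, so other dispersions could rank the tools otherwise. The changed genes were drawn from those with a mean over 1 CPM, so these rates do not cover genes of lower counts.

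As fewer than 5 genes passed edgeR's threshold in either direction, the 5 genes of smallest p stand in for each; all had an edgeR adjusted p of 0.455, none overlapped between the groups, and DESeq2 called all 10. Among those with higher values, Clec7a, a receptor for fungal glucans on myeloid cells, had 13.3 ± 3.02 CPM in vehicle and 67.5 ± 25.6 CPM in GSK3326595 (SD, n = 3 each; log2 difference 2.34 ± 0.33). Col5a3, a fibrillar collagen chain, had a log2 difference of 2.37 ± 0.32, and Akr1e1, an aldo-keto reductase, of 2.18 ± 0.30. Cd247, the zeta chain of the T cell receptor complex, differed by 3.27 ± 0.46, and Siglech, a lectin of plasmacytoid dendritic cells, by 3.20 ± 0.46. Among those with lower values, Shank2, a scaffold protein, had 32.2 ± 9.99 against 5.004 ± 0.583 CPM (-2.69 ± 0.30), and Jund, a member of the AP-1 transcription factors, 30.2 ± 1.09 against 12.8 ± 1.95 CPM (-1.23 ± 0.19). Stx1a, a syntaxin, differed by -2.43 ± 0.40, Scml4 by -3.31 ± 0.56 and Itih5, a hyaluronan-binding inhibitor family member, by -1.82 ± 0.33.

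**Figure D2:**
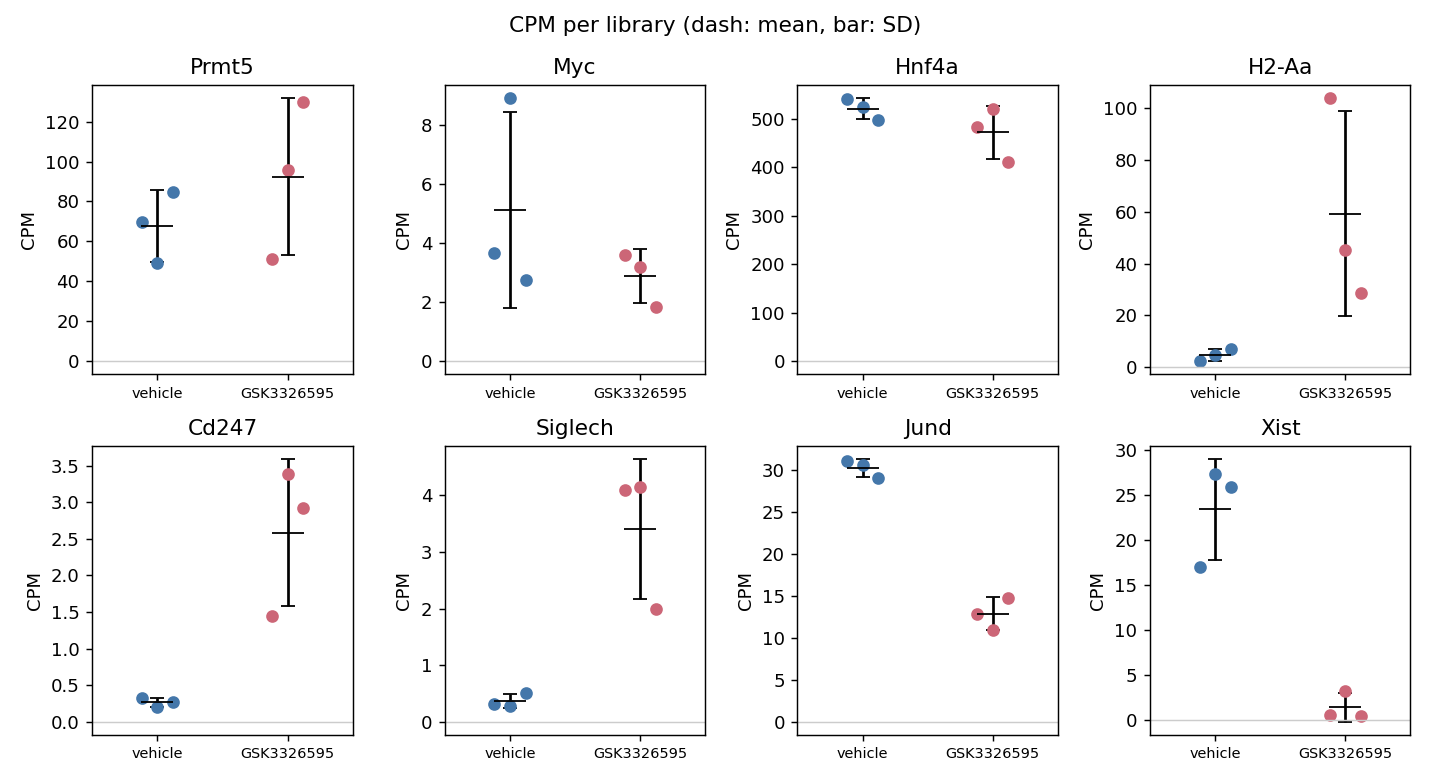
CPM (vertical, linear) of 8 genes in the 3 vehicle and 3 GSK3326595 libraries; each point is a library, the dash is the group mean and the bar the SD. Prmt5, Myc and Hnf4a overlapped between the groups, while H2-Aa, Cd247, Siglech, Jund and Xist did not.

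Of 44 gene lists fixed before the data were examined, 43 could be tested. Camera with a preset correlation called 6 lists higher and 4 lower in GSK3326595, the higher ones being led by antigen presentation and by markers of T, NK and dendritic cells. None of the 10 calls held with an estimated correlation, where the smallest adjusted p over all lists was 0.947, and fry's directional test called 0 lists (smallest adjusted p 0.206). Its mixed test, which asks whether members change in either direction and does not compare a list with other genes, passed for the T cell and sex chromosome lists (adjusted p = 0.0362 each). The same camera test called between 14 and 28 lists in each of the other 9 ways of splitting these libraries 3 against 3, so the number of calls does not set the treatment apart from other groupings. A comparison of 3 against 3 libraries cannot give an exact permutation p under 0.1.

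Antigen presentation genes were higher in GSK3326595 in all 18 measured members, with a median log2 difference of 2.53 (camera adjusted p = 1.36e-13; adjusted p = 0.947 with an estimated correlation). By edgeR 14 members passed adjusted over the list alone and 0 over all genes, while 14 had an unadjusted p under 0.05 and DESeq2 called 12. H2-Aa, a chain of MHC class II, had 4.74 ± 2.31 CPM in vehicle and 59.3 ± 39.6 CPM in GSK3326595 (SD, n = 3 each; log2 difference 3.64 ± 0.62). Its partner H2-Ab1 had 6.35 ± 2.63 against 89.1 ± 70.4 CPM (3.81 ± 0.66), and H2-DMa, which loads peptides onto class II, 1.21 ± 0.299 against 8.81 ± 5.001 CPM (2.86 ± 0.51). The members' mean log2 CPM was 2.22, 2.83 and 2.94 in the vehicle libraries and 5.21, 5.08 and 3.72 in the GSK3326595 libraries, the smallest exact permutation p that n = 3 against 3 allows (0.1, two-sided).

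Markers of lymphoid and dendritic cells were higher as well, at low levels. All 13 T cell markers kept by the filter, of 18 fixed, had higher values (median log2 difference 2.43). The camera adjusted p was 1.36e-13, or 0.947 with an estimated correlation. The filter could keep a marker by the treated libraries alone, which favours higher values. By edgeR 10 passed adjusted over the list alone, and 15 of 18 with no filter on low counts (median 2.46). Cd6 differed by 3.08 ± 0.56, Cd2 by 2.78 ± 0.56 and Cd28 by 2.67 ± 0.54. Cd247 had only 0.264 ± 0.0574 CPM in vehicle and 2.58 ± 1.01 CPM in GSK3326595 (SD, n = 3 each). Among 12 NK and cytotoxic markers 11 were higher (median 2.29; camera adjusted p = 3.47e-08), 7 past the threshold adjusted over the list alone, and Klrd1, an NK receptor chain, differed by 2.85 ± 0.50, Nkg7 by 2.47 ± 0.52 and Klrk1 by 2.29 ± 0.49. All 9 dendritic markers were higher (median 2.04; camera adjusted p = 2.66e-08), 6 past the threshold adjusted over the list alone, with Itgax at 1.61 ± 0.32 and Flt3, a receptor for dendritic precursors, at 2.45 ± 0.60. Each of these lists had an adjusted p of 0.947 with an estimated correlation, and 0 members passed over all genes by edgeR, against 11, 9 and 6 at an unadjusted p under 0.05 and 9, 5 and 3 by DESeq2. Without vehicle replicate 1 the members past adjustment over the list alone came to 3 for NK and 2 for dendritic markers, and without GSK3326595 replicate 1 to 4 for NK markers. A filter of at least 1 CPM in 3 libraries left 4 T cell and 4 NK markers, too few for the list test, and 5 dendritic markers with a median of 1.23, 2 of them past adjustment over the list alone.

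Markers of B and plasma cells (9 of 10 higher, median 0.52; camera adjusted p = 0.0818), macrophages (14 of 18 higher, median 0.53; camera adjusted p = 0.231) and endothelium (11 of 16 higher, median 0.33; camera adjusted p = 0.379) were not called. The B and plasma cell list was called higher without vehicle replicate 1 (camera adjusted p = 0.0299), vehicle replicate 3 (0.007) or GSK3326595 replicate 3 (0.000135), in a range up to 0.553 over the left-out libraries. Of the B lineage, Ighm differed by 2.43 ± 0.59 and Igkc by 2.29 ± 0.68. The macrophage median was -0.07 without GSK3326595 replicate 1, and the test of endothelial markers turned lower without vehicle replicate 1 (camera adjusted p = 0.98) and GSK3326595 replicate 2 (0.465), though neither list was called without any library. Of other lists, the interferon-stimulated genes had 22 of 30 members higher (median 0.52; camera adjusted p = 0.0969), called higher without vehicle replicate 2 (0.00752) or GSK3326595 replicate 3 (1.07e-05) and reaching 0.917 without vehicle replicate 1. Markers of stellate cells and fibroblasts were called higher, 16 of 18 with a median of 0.92 (camera adjusted p = 1.27e-05; adjusted p = 0.947 with an estimated correlation). By edgeR 0 members passed adjusted over the list alone or over all genes, 5 had an unadjusted p under 0.05, and DESeq2 called 0. The median was 0.53 without vehicle replicate 1 and 1.46 without vehicle replicate 3, where 9 of the 18 members passed adjusted over the list alone. Col6a3 had 38.6 ± 13.7 against 84.5 ± 10.5 CPM (SD, n = 3 each; 1.13 ± 0.28), and Col1a2 a log2 difference of 1.13 ± 0.43.

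**Figure D3:**
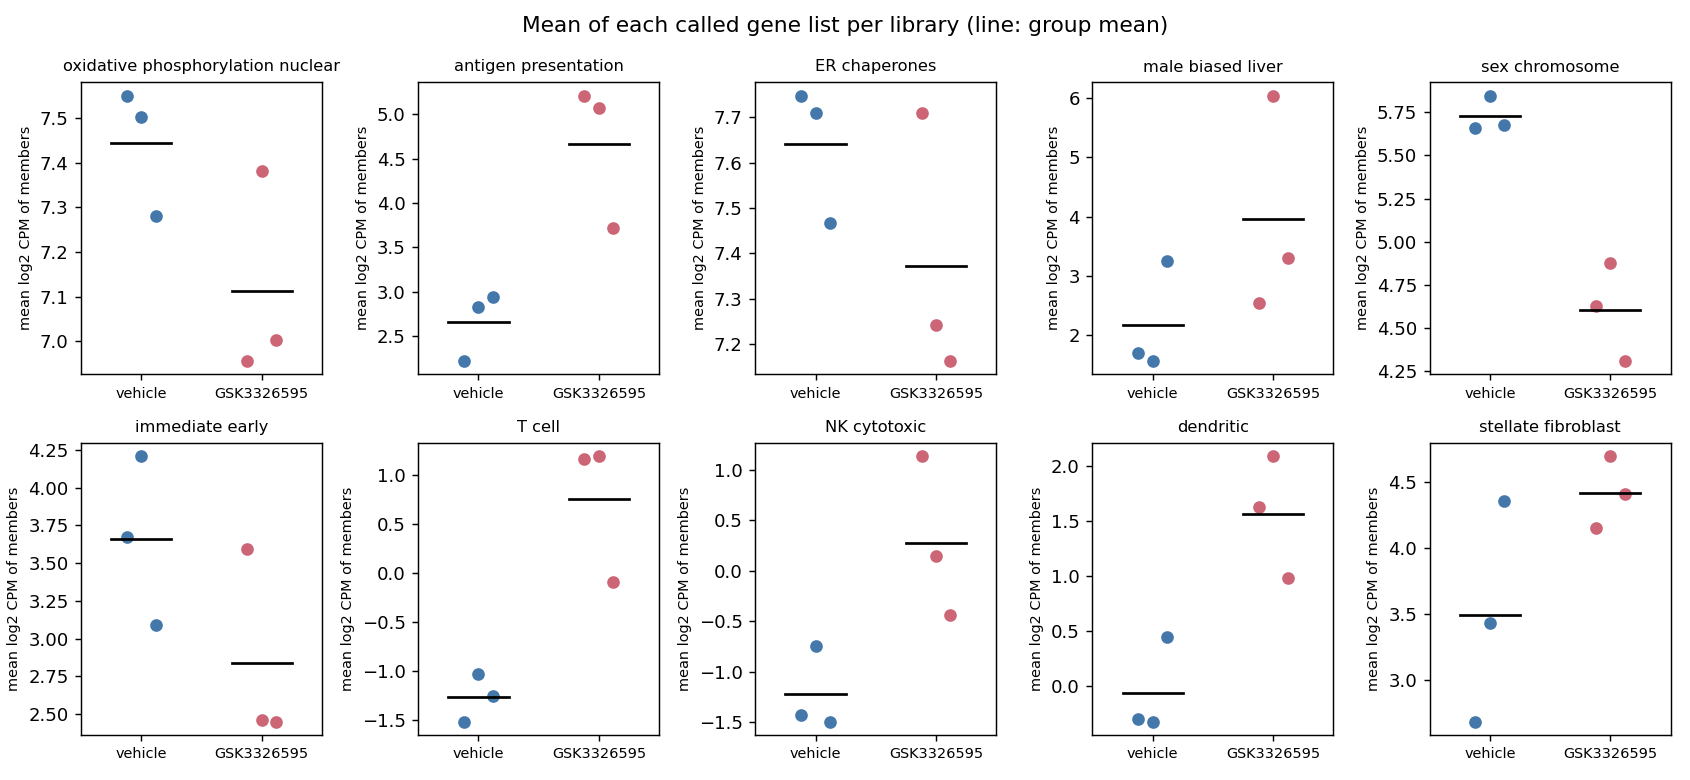
Mean log2 CPM (vertical; axes do not start at 0) of the members of the 10 called gene lists in each library, by group; each point is a library and the line the group mean. The libraries of the groups do not overlap for antigen presentation, T cell, NK, dendritic and sex chromosome genes, and do overlap for the other 5 lists.

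Nuclear genes of oxidative phosphorylation were lower in 26 of 27 members, by a median log2 difference of -0.31 (camera adjusted p = 6.61e-07; adjusted p = 0.947 with an estimated correlation). Atp5o had 311 ± 39.6 CPM in vehicle and 201 ± 11.3 CPM in GSK3326595 (SD, n = 3 each; -0.63 ± 0.17), and Cox8a differed by -0.53 ± 0.19. By edgeR 0 members passed adjusted over the list alone or over all genes, 6 had an unadjusted p under 0.05, and DESeq2 called 0. Immediate early genes, which respond to stimuli and to handling of tissue, were lower in 15 of 16 members (median -0.93; camera adjusted p = 6.25e-06; adjusted p = 0.947 with an estimated correlation). Jund and Jun passed edgeR's threshold adjusted over the list alone, Jun with 87.2 ± 10.8 against 41.5 ± 12.7 CPM (-1.07 ± 0.25). That count of 2 was 0 without vehicle replicate 1, 1 without vehicle replicate 2, GSK3326595 replicate 2 or GSK3326595 replicate 3, and 6 without vehicle replicate 3. Chaperones of the endoplasmic reticulum were lower in 14 of 16 members (median -0.16; camera adjusted p = 0.0464; adjusted p = 0.947 with an estimated correlation), a call kept without vehicle replicate 3 or GSK3326595 replicate 1 and lost without any other library (camera adjusted p from 0.0721 to 0.261). Their median was -0.05 without GSK3326595 replicate 2, -0.09 without GSK3326595 replicate 3, -0.25 without vehicle replicate 3 and -0.26 without GSK3326595 replicate 1. With no scaling beyond total counts it was -0.07, where the median of all genes was 0.12 against 0.03 with TMM. By edgeR 0 of these chaperones passed adjusted over the list alone or over all genes, 2 had an unadjusted p under 0.05, and DESeq2 called 0; without GSK3326595 replicate 1, 2 passed adjusted over the list alone.

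Genes with male-biased expression in liver were higher in 11 of 12 members (median 2.28; camera adjusted p = 0.00803; adjusted p = 0.947 with an estimated correlation). By edgeR 0 members passed adjusted over the list alone or over all genes, 5 had an unadjusted p under 0.05, and DESeq2 called 3. GSK3326595 replicate 2 set this call: without it the median was 0.58 and the camera adjusted p 0.201. Without vehicle replicate 3 the median was 3.94, and 1 member passed adjusted over the list alone, against 5 without GSK3326595 replicate 1 and 6 without GSK3326595 replicate 3. With no filter on low counts 7 of 16 members passed so. The sex chromosome list, which pools Xist with Y-linked genes, was lower in all 5 members (camera adjusted p = 0.00818, or 0.947 with an estimated correlation). Its median log2 difference was -0.29 and its mean -1.02, as Xist pulled the mean down. Xist, the noncoding RNA of X inactivation (chromosome X, 103460366 to 103483254, minus strand), alone passed edgeR's threshold adjusted over the list alone. Xist had 17.0, 27.4 and 25.9 CPM in the vehicle libraries and 0.516, 3.26 and 0.433 CPM in the GSK3326595 libraries (-4.05 ± 0.84, edgeR adjusted p = 0.455 over all genes). It overlaps the antisense gene Tsix, and whether counting used strand is not given in the sources used here. The Y-linked Eif2s3y was present in all libraries, with 58.3 ± 3.95 against 44.5 ± 3.87 CPM (SD, n = 3 each; -0.39 ± 0.15).

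Lists of proliferation and of MYC targets did not pass in the unblocked camera test of all 6 libraries, and single libraries turned both calls and directions. Replication genes had a median log2 difference of 0.07 (camera adjusted p = 0.847), mitosis genes -0.09 (0.0818), ribosome biogenesis genes 0.16 (0.529) and other MYC targets 0.09 (0.874), whose test pointed the other way from their median. Without GSK3326595 replicate 3, mitosis genes (camera adjusted p = 3.38e-09), replication genes (0.0113) and other MYC targets (0.0166) were called lower. Without GSK3326595 replicate 1, ribosome biogenesis genes (camera adjusted p = 3.14e-05) and other MYC targets (0.0305) were called higher. Replication genes were called higher without vehicle replicate 3 (camera adjusted p = 0.0268), and mitosis genes lower without vehicle replicate 2 (0.00109). Over the left-out libraries the largest adjusted p was 0.661 for mitosis, 0.98 for replication, 0.84 for ribosome biogenesis and 0.98 for other MYC targets. The PRMT family with partners of PRMT5 (0.12, camera adjusted p = 0.47), p53 targets (0.15, 0.529) and splicing factors (0.03, 0.967) were not called either, though the PRMT list was called higher without GSK3326595 replicate 1 (camera adjusted p = 0.00734, up to 0.952 without other libraries) and splicing factors lower without GSK3326595 replicate 3 (0.0389, up to 0.98). Of single members, Eda2r, a p53 target, had 2.72 ± 1.38 against 13.5 ± 6.21 CPM (SD, n = 3 each; log2 difference 2.31 ± 0.56, edgeR adjusted p = 0.455), and Shmt2, of serine metabolism, 333 ± 41.4 against 196 ± 37.8 CPM (-0.76 ± 0.21, edgeR adjusted p = 0.459).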

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

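DESeq2 on fewer libraries, the removal of further abundant noncoding RNAs and the counts of list members under other settings were chosen after seeing the data. The counts of 0 genes higher and 0 lower by edgeR stood under every scaling, filter and threshold tried, under the replicate block and without each library. The 927 and 648 at an unadjusted p under 0.05 did not: they turned to 638 and 779 under the replicate block, and without each library ranged from 347 to 1629 higher and from 241 to 961 lower. DESeq2 called 204 higher and 111 lower, limma-voom 0 and 0, and limma-voom with sample quality weights 1 higher and 0 lower; the cause was not tested. Without each library in turn DESeq2 called from 37 to 516 genes higher and from 21 to 223 lower. Of the 315 genes called with all 6 libraries, 48 were called again without vehicle replicate 1 and 264 without GSK3326595 replicate 3.

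The 6 higher and 4 lower gene lists became 0 and 0 with an estimated correlation, the only setting changed. That correlation was 0.38 to 0.772 in the called lists, against the preset 0.01. The estimated form also gave larger p where genes were drawn independently. There, a simulated list of 30 genes raised 2-fold had camera p = 1.04e-18 with the preset and 0.000553 with an estimated correlation. The loss of calls therefore cannot be put down to members varying together alone. The 6 higher and 4 lower lists also became 0 and 0 by fry's directional test, for which the cause was not tested. Without each library they ranged from 5 to 12 higher and from 5 to 16 lower, with fewer samples in each fit. Antigen presentation, T cell, NK, dendritic, stellate, oxidative phosphorylation, immediate early and sex chromosome lists were called in all 6 of these fits. Requiring at least 1 CPM in 3 libraries ended the T cell and NK calls, as too few markers were left, and the endoplasmic reticulum chaperone call (camera adjusted p = 0.0614). Leaving out mitochondrial, rRNA and further abundant noncoding RNAs added lipogenesis, pericentral WNT genes (camera adjusted p = 0.0478 each) and B and plasma cell markers (0.0282) to the higher lists and cholesterol synthesis (0.0495) to the lower. With the replicate block 7 lists were higher and 10 lower, adding lipogenesis (camera adjusted p = 0.0231) to the higher and mitosis (0.0451), secreted hepatocyte proteins (0.0036), urea cycle (0.0209), amino acid catabolism (0.00695), acute phase (0.0132) and neutrophil markers (0.0132) to the lower; 5 stellate, 4 immediate early and 2 male-biased genes then passed adjusted over the list alone. The replicate numbers share only a number: same-numbered libraries' deviations correlated at -0.073, 0.072 and 0.323, and not every library correlated best with its own number. All 39 genes named by the rule kept their direction in every scaling, tool, filter, block and left-out library tried for single genes, though most were chosen for a small p. Depth limits the lymphoid markers, many of which lay under 1 CPM in vehicle.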

Other observations

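Of the tests of explanations given below, only the splits of the libraries and the test of X-linked genes were set before their results were seen. The others were chosen after, while the gene lists and their camera test were fixed beforehand. Lipogenesis, bile acid and xenobiotic genes spread widely between the GSK3326595 libraries, and their lists did not pass in the unblocked camera test of the 17012 genes in all 6 libraries. Lipogenesis genes were higher in 17 of 20 members (median log2 difference 0.45; camera adjusted p = 0.0517), and were called without vehicle replicate 1 (0.00949) or GSK3326595 replicate 1 (0.000257), in a range up to 0.279 over the left-out libraries. Among them was Me1, malic enzyme, at 4.20 ± 0.684 CPM in vehicle and 52.0 ± 54.4 CPM in GSK3326595 (SD, n = 3 each). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 6.94 ± 5.72 against 69.2 ± 71.1 CPM. Its list (camera adjusted p = 0.949) was called lower without GSK3326595 replicate 2 (0.00242) and reached 0.917 without vehicle replicate 1. Xenobiotic metabolism genes had a median of 1.78 (camera adjusted p = 0.0818), which was -0.06 without GSK3326595 replicate 2 (0.0603, lower); the list was called higher without GSK3326595 replicate 1 (0.000223) or GSK3326595 replicate 3 (0.0169). Pklr, a glycolytic kinase in the gluconeogenesis and glycogen list, alone passed edgeR's threshold adjusted over that list alone (30.01 ± 6.18 against 86.4 ± 20.8 CPM). Neutrophil markers had a median of -3.03 (camera adjusted p = 0.179), which was -0.03 without vehicle replicate 2 (0.832), and were called lower without vehicle replicate 1 (0.00194), vehicle replicate 3 (0.000424) or GSK3326595 replicate 2 (0.0201); S100a9 had 85.7 CPM in vehicle replicate 2 and at most 2.73 CPM in the other libraries.

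In that test 16 further lists did not pass either (camera adjusted p from 0.0517 to 0.967), but each was called without 1 library or more, and each reached at least 0.499 without another. Without GSK3326595 replicate 2, amino acid catabolism (9.9e-07), urea cycle (0.000103), acute phase (0.000168), gluconeogenesis and glycogen (0.000549), female-biased (0.000893), periportal (0.0014) and fatty acid oxidation genes (0.00592) were called lower. So were secreted hepatocyte proteins (0.0014), liver transcription factors (0.00242), cholesterol synthesis (0.00646) and erythroid markers (0.000549). Without vehicle replicate 3, acute phase (0.0041), amino acid catabolism (0.00429), secreted protein (0.00429), urea cycle (0.0127), serine and one-carbon (0.0127), periportal (0.0154), mitochondrially encoded (0.0267) and female-biased genes (0.0271) were called lower. Without GSK3326595 replicate 1 secreted protein (0.0137) and serine and one-carbon genes (0.0181) were called lower. Without GSK3326595 replicate 3 cholesterol synthesis (0.000138), serine and one-carbon (0.0235), DNA repair (0.0237) and nonhepatic glycolysis genes (0.0365) were called lower. Cholesterol synthesis was called lower without vehicle replicate 2 (0.00434) and erythroid markers without vehicle replicate 1 (0.00044). Pericentral WNT genes were called higher without vehicle replicate 3 (0.00179), GSK3326595 replicate 1 (0.00121) or GSK3326595 replicate 3 (0.0235). With all 6 libraries the medians of gluconeogenesis (0.01), fatty acid oxidation (0.19), periportal (0.08), female-biased (0.09) and DNA repair genes (0.09) were above 0 while their test pointed lower.

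The 10 splits of the 6 libraries into 3 and 3 cannot give a share under 0.05. The real split gave 0 genes by edgeR (highest other 0; 10 splits as large, the real one included), and 1575 at an unadjusted p under 0.05 (highest other 2080; 4 splits as large). DESeq2 gave 315 genes (highest other 561; 3 splits as large). Camera gave 10 lists, the fewest of any split (highest other 28; 10 splits as large). Members past adjustment over the list alone, summed over all lists, came to 42 (highest other 77; 4 splits as large).

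Antigen presentation genes and markers of T, NK and dendritic cells were higher together in GSK3326595, and a higher depth there is argued against by the library totals, which differed by -2937951 expected counts on average. A lower share of hepatocyte-lineage cells would raise markers of all other cell types alike, if those types kept their proportions to each other. However, the T cell median exceeded that of 61 macrophage, endothelial, stellate and cholangiocyte markers by 1.86 on the log2 scale (permutation p = 1e-05 over genes). That p is the smallest these permutations can give, and it is too small because markers vary together. The gap between the T cell mean and the mean of those markers was wider in every vehicle library (-5.19 to -4.38) than in any treated one (-3.78 to -2.56). Stellate markers, called higher, do go with a lower share, as does the median of 0.57 of the 61 markers together. Hepatocyte gene lists went both ways with all 6 libraries. Secreted proteins were lower in 20 of 30 members and liver transcription factors in 14 of 22, while xenobiotic genes were higher in 25 of 30. That xenobiotic rise rested on GSK3326595 replicate 2. The mean log2 CPM was 7.18 there, 2.99 and 4.09 in the other treated libraries, and 3.31 to 4.58 in vehicle. Without that replicate the xenobiotic median was below 0. Secreted proteins and liver transcription factors were then called lower, which goes with a lower share. None of these lists was called in the unblocked camera test of all 6 libraries. The T cell gap therefore argues only against a lower share, at fixed proportions of the other types, as the whole cause. Lymphoid tissue in the treated pieces stays open: the T cell median also exceeded that of B and plasma cell markers by 1.91 (permutation p = 0.00053 over genes), but 3 of those 10 markers, Ighm and Igkc among them, moved with the T cell markers, and the list was called higher without vehicle replicate 1 (camera adjusted p = 0.0299), vehicle replicate 3 (0.007) or GSK3326595 replicate 3 (0.000135), in a range up to 0.553. The treatment itself also stays open, as untested.

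Xist was higher in every vehicle library than in any GSK3326595 library while Y-linked genes were present in all. Female tissue in the vehicle libraries would lower their Y-linked genes, whose mean log2 CPM differed by -0.27 (GSK3326595 minus vehicle), the opposite direction; a small share would not show against so high a baseline, so the explanation stays open. If Xist RNA acted on the X chromosome in vehicle, X-linked genes would be higher in GSK3326595. The median of 504 X-linked genes exceeded that of 16420 autosomal genes by 0.071 (95% bootstrap interval 0.0385 to 0.115; permutation p = 4e-04 over genes, which are not independent), in that direction but below the bound of 0.1 set beforehand. The interval includes that bound, so the test leaves it open.

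Afp, a fetal liver gene named after its values were seen, was low in GSK3326595 replicate 2, at a log2 ratio of -4.32 to the median of the other libraries. Non-tumor liver mixed into that library would lower other tumor transcripts by a like factor, if it held as little of them as of Afp. No library of non-tumor liver was at hand to check that condition. H19 lay at 0.16 and the median mitosis gene at -0.38, so the smaller of these exceeded Afp by 3.94. Only under that condition does this argue against admixture as the whole cause of low Afp. A smaller share stays open: the mean log2 CPM of xenobiotic genes was 7.18 there, 2.60 above the highest other library, that of bile acid genes 6.99 against 3.79 to 5.11, that of male-biased genes was 6.04 against 1.56 to 3.30, and that of the oncofetal list 3.79 against 4.78 to 5.37, while mitosis genes were not lowest there (5.82, lowest 5.47). That a few genes took most of the counts is argued against by the share of the 10 most abundant genes, 16.01% there and 14.55% to 18.45% in the other libraries; no biological explanation was tested.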
